A study of Mus musculus with 9 samples.

How the data were processed

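RNA sequencing measured transcript levels in 9 mouse liver libraries, 3 in each of 3 groups. Each library is treated as the liver of a separate mouse, which the labels' replicate numbers imply without naming animals. Groups were taken from the sample titles, which read WT pair-fed, WT EtOH-fed and Mettl3OE EtOH-fed and name no virus. The groups are called pair-fed mice with the control virus, ethanol-fed mice with the control virus, and ethanol-fed mice with the Mettl3 virus. No label gives a sequencing date or batch. Choices of test, filter, gene lists and named genes were made before the data were examined, except where stated otherwise.

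Per the submitters' processing notes, reads were handled with fastp, HISAT2 and HTSeq on mouse build mm10; no versions are given and the strand setting of the counting is not stated. The authors deposited 2 tables, each holding 2 groups and 6 libraries, with FPKM (reads scaled to gene length and library total) for every library. Per the file headers, the tables also hold a signal column, the mean of read counts divided by size factors, overall and per group, named after DESeq2. The deposited linear fold (ratio) and its log2 were made by the authors for ethanol-fed against pair-fed livers in the first table and for Mettl3 against control virus in the second. The deposited p-value and q-value columns come from the authors' DESeq2 test, per the file headers, and q equals the Benjamini-Hochberg adjustment of p over each table. The tables held 16842 and 16470 genes, of which 16266 are in both. The ethanol-fed columns are in both tables and differed by a relative 1.08e-06 at most, so that all 9 libraries are on a common scale. The files give gene symbols and Entrez numbers. Of 17046 gene numbers, 16795 matched the mouse GRCm38 RefSeq annotation, from which chromosome, start and end were taken.

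Because the values were FPKM, the test foreseen for read counts was replaced by the one foreseen for FPKM. It was limma's moderated test (lmFit and eBayes with trend and robust settings; limma 3.58.1 in R 4.3.3) on log2(FPKM + 1), for genes with FPKM of at least 1 in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is therefore on the log2(FPKM + 1) scale, which understates the change of low genes. Ethanol-fed minus pair-fed livers and Mettl3 minus control virus under ethanol were each fitted on their own 6 libraries, and Mettl3 livers minus pair-fed livers in a fit of all 9. The numbers of genes tested were 10064, 9706 and 10229. Values are means ± SD over n = 3 livers; SE is the standard error of the log2 fold change. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.

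Depth was recovered from the deposited values. Steps in the signal columns and FPKM gave whole reads for 100% of genes within a tolerance of 0.05. Totals over the listed genes ran from 34656256 to 38159563 reads per library. FPKM denominators followed those totals, so a scaling by total counts would repeat the FPKM scale and was not run separately. Alternatives that need a count test were not run, since the deposited unit is FPKM. In their place limma-voom was run on the recovered reads.

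A total of 42 gene lists was fixed in advance, covering ethanol and drug oxidation, lipid, sterol, bile acid, glucose and methionine metabolism, stress, inflammation, the clock, sex-biased and zonated genes, respiration, ribosomal proteins, m6A enzymes and readers, and markers of other liver cell types. Of these, 38, 37 and 38 had at least 3 tested members in the respective comparisons. They were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry, adjusting over the lists tested. Members were counted as higher, lower or not called from the gene test, over all genes and adjusted over the list alone. No pathway database was searched. The planned exact test of calls shared by the effects was not run, as the Mettl3 effect gave a single call.

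The text names Mettl3 first, then up to 10 higher and 10 lower genes with the largest fold change among called genes whose groups do not overlap and whose higher group has a mean FPKM of at least 1, predicted genes aside. Where fewer passed, up to 5 per direction with the smallest unadjusted p were added, with values only. For lists that were called or held a called member, up to 4 members with the smallest p could be named, and only some of them are; the values of some single genes are not reported here. Other genes are marked where they were chosen after their values were seen.

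The fits were tested on simulated data with 200 genes changed among the real genes, in 10 draws per comparison, with genes simulated independently. Ethanol-fed against pair-fed livers recovered 71.8% of 2-fold and 92.4% of 4-fold changes, over a mean of 9996 genes. The Mettl3 comparison recovered 52.5% and 86.8% over a mean of 9699 genes. Mettl3 against pair-fed livers recovered 68.2% and 91.8% over a mean of 10081 genes. False calls made up 6.37%, 6.06% and 5.44% of all calls, respectively. A list holding changed genes was called in 10 of 10 draws of each. With 200 genes changed, the Benjamini-Hochberg threshold is easier to pass than where few genes change. The recovery rates therefore need not hold for the real Mettl3 comparison. There Rgs16, at 137 FPKM with the control virus and 7.99 FPKM with Mettl3, did not pass.

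Alternatives set in advance were a pseudocount of 0.1, no filter, a single fit of 9 libraries, the replicate number as a block, a test against a 1.2-fold change, and leaving out each library in turn. Alternatives chosen after seeing the data were median-ratio scaling, limma-voom on recovered reads with either scaling, a filter of at least 50 mean reads, library quality weights, and a fit of 6 libraries for Mettl3 against pair-fed livers. Correlation between the effects was set beside 100 simulated draws in each of 2 cases.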

Results

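Liver transcripts were measured by RNA sequencing in 9 mice in 3 groups of 3. An adeno-associated virus with a hepatocyte promoter carried either a control insert or Mettl3, which encodes the catalytic subunit of the nuclear m6A methyltransferase. Feeding began 3 weeks after injection and lasted 10 days on a control or an ethanol diet, closing with a single binge of maltose or ethanol. Total reads over the listed genes were between 34656256, in ethanol-fed liver 1, and 38159563, in Mettl3 liver 3. On log2(FPKM + 1), PC1 held 70.8% of the variance and PC2 12.7%. Pair-fed livers correlated with each other at Pearson's r across genes of 0.991 to 0.994. The lowest values within a group were 0.972 both for ethanol-fed livers 1 and 2 and for Mettl3 livers 2 and 3.

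**Figure D1:**
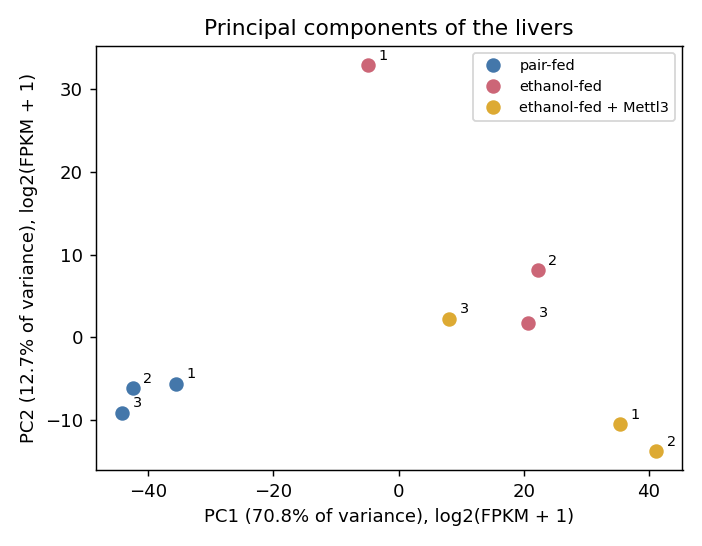
Principal components of log2(FPKM + 1) over 10229 genes, 1 point per liver, numbered by replicate. The 3 pair-fed livers lie between -35.6 and -44.1 on PC1, ethanol-fed liver 1 lies at -4.94, and Mettl3 livers 1 and 2 lie at 35.3 and 41.1. Mettl3 liver 3 lies at 7.99, below ethanol-fed livers 2 and 3 at 22.2 and 20.6.

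Mettl3 (Entrez 56335, chromosome 14, 52294841 to 52308741, GRCm38) was at 3.48 ± 0.447 FPKM in pair-fed livers and 4.69 ± 0.842 in ethanol-fed livers with the control virus (SD, n = 3 each). It was at 32.2 ± 6.81 FPKM in ethanol-fed livers with the Mettl3 virus (SD, n = 3), where the lowest liver had 24.98 and the highest control-virus liver 5.44. Between ethanol-fed and pair-fed livers its log2 fold change was 0.34 (SE 0.14), which did not pass, with limma's adjusted p at 0.0947. Of the ethanol-fed livers, 2 lay above all 3 pair-fed ones. Median-ratio scaling gave 0.48 with adjusted p 0.0175, and leaving out ethanol-fed liver 3 gave 0.46 with adjusted p 0.0387. Adjusted p ranged from 0.0175 to 0.707 over the alternatives. In the authors' DESeq2 test of the same livers Mettl3 passed, with a log2 fold change of 0.61 and q of 0.00602. That fold change is not on the log2(FPKM + 1) scale.

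**Figure D2:**
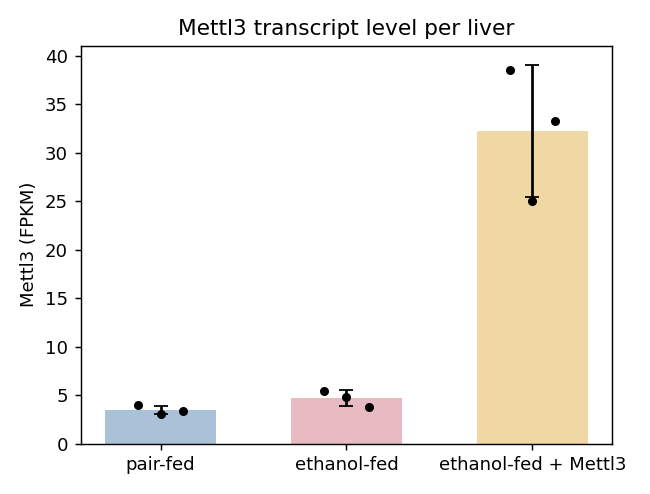
Mettl3 level in FPKM for each group. Bars are means, error bars SD and points single livers (n = 3 per group). The Mettl3 livers lie between 24.98 and 38.49 FPKM, above every other liver.

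The first comparison asked how chronic ethanol feeding with a binge changed the liver in control-virus mice. Serum amyloid A2 (Saa2), an acute phase transcript that hepatocytes make under inflammatory cytokines, had the largest rise of all genes tested. It went from 27.0 ± 8.91 to 5236 ± 3747 FPKM (SD, n = 3 each; log2 fold change 7.12, SE 0.74). Cyp2e1, a microsomal ethanol oxidase, fell from 5021 ± 610 to 1395 ± 140 FPKM (log2 fold change -1.84, SE 0.13). Adh4, an alcohol dehydrogenase, fell from 52.97 ± 3.18 to 8.21 ± 1.00 FPKM (log2 fold change -2.56, SE 0.11). Ddit3, which encodes the stress transcription factor CHOP, rose from 2.28 ± 0.291 to 19.1 ± 5.97 FPKM (log2 fold change 2.58, SE 0.20). In limma these 4 had adjusted p of 0.00125, 0.000479, 0.000172 and 0.000504, with all 3 ethanol-fed livers beyond all 3 pair-fed ones.

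Of 10064 genes tested, 3625 passed in limma after Benjamini-Hochberg adjustment, 1009 higher and 2616 lower, and 4787 had an unadjusted p below 0.05. At 2-fold or more, 248 were higher and 386 lower, against 341 and 266 under median-ratio scaling. With a pseudocount of 0.1 these counts were 361 and 660, and with limma-voom on recovered reads 362 and 708. The median log2 fold change of all genes was -0.14. Median-ratio scaling moved it to 0.00 and gave 1729 genes higher and 1783 lower, so that 50.8% of calls were lower in place of 72.2%. The count fell to 2157 without pair-fed liver 1, 1538 without pair-fed liver 2, 1541 without pair-fed liver 3 and 2392 without ethanol-fed liver 2. It was 4743 without ethanol-fed liver 1. The authors' table lists 4478 genes at q under 0.05, 2361 higher and 2117 lower. Of the 3584 among them that were tested here, 2676 were also called here in the same direction and 0 in the opposite direction. Both tests used the same livers, so the overlap is not independent support.

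Among the 10 genes that rose furthest with no overlap of the groups (chance 10% per gene), Saa2, Saa1, Lcn2, Orm2 and Orm3 were on the acute phase list. Lcn2 was on the neutrophil list as well. Saa1 followed Saa2 at a log2 fold change of 6.64 (SE 0.64), from 42.8 ± 15.1 to 5405 ± 3554 FPKM. Lipocalin 2 (Lcn2) rose by 5.72 (SE 0.66), from 28.0 ± 22.3 to 1516 ± 881 FPKM. Orm2 and Orm3 rose by 4.42 and 3.34. The metallothioneins Mt2 and Mt1 rose by 4.71 and 4.26, and Igfbp1, an insulin-repressed gene, by 4.69. Cyp2b10, the classical target of the receptor CAR, rose by 3.48 from 0.381 ± 0.0238 FPKM. The hepatokine Fgf21 rose by 3.32 (SE 0.62), from 5.89 ± 1.22 to 94.1 ± 96.2 FPKM. Ethanol-fed liver 1 moved several of these values. Without it the log2 fold change was 8.08 for Saa2, 7.45 for Saa1, 6.39 for Lcn2 and 2.52 for Fgf21, and without pair-fed liver 1 it was 6.31 for Lcn2. Saa1 and Saa2 are near-identical copies, so their split is uncertain, as it is for Orm2 with Orm3.

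The 10 genes that fell furthest by the same rule were led by the acyl-CoA thioesterases Acot3 (log2 fold change -5.04, SE 0.43) and Acot1 (-3.41, SE 0.23), neighbours on chromosome 12 that can share reads. Acot3 went from 108 ± 15.5 to 2.84 ± 2.79 FPKM. The clock output gene Dbp followed at -2.92 (SE 0.35), then Fbxo21 at -2.72, the transporter Slco1a1 at -2.69 and Keg1 at -2.67. Depp1, Rnf186, Adh4 and Tbx3os1 lay between -2.61 and -2.51. Tbx3os1 is antisense to Tbx3, and without a stated strand setting their reads cannot be told apart. Adjusted p of the 10 higher and 10 lower genes stayed below 0.05 without any single library, at most 0.0463 for Fgf21 among the higher and 0.0347 for Slco1a1 among the lower.

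Acute phase proteins had 20 of 24 members higher, 0 lower and 4 not called, with 21 higher when adjusted over the list alone, and a median log2 fold change of 1.47 (1.65 under median-ratio scaling). The unfolded protein and integrated stress response had 17 of 22 higher, 0 lower and 5 not called, with 19 higher when adjusted over the list alone, at a median of 1.28. Atf4, Chac1 and Xbp1 rose by 0.97, 2.53 and 1.18. Immediate early genes, which respond to signals without new protein synthesis, had 7 of 13 higher, 0 lower and 6 not called, with 8 higher when adjusted over the list alone. Jun rose by 1.63 and Btg2 by 2.76. Camera gave these 3 lists adjusted p of 1.92e-12, 7.14e-12 and 2.99e-06 at the preset correlation; for each, adjusted p = 0.763 with an estimated correlation.

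Fatty acid oxidation, the pathway that burns fat in mitochondria under PPARalpha, moved down. In that list 25 of 28 members were lower, 1 higher (Fgf21) and 2 not called, with 26 lower and 1 higher when adjusted over the list alone, at a median of -0.86 (-0.69 under median-ratio scaling, with 23 lower). Acaa1b, Vnn1 and Slc25a20 fell by 2.01, 1.45 and 0.94 on the log2 scale. Cholesterol synthesis had 18 of 25 lower, 1 higher and 6 not called, with 19 lower and 1 higher when adjusted over the list alone (14 and 1 under median-ratio scaling). Insig1, an SREBP2 target, fell by 1.99. Alcohol and aldehyde oxidation had 11 of 15 lower, 1 higher and 3 not called, with 12 lower and 1 higher when adjusted over the list alone (7 and 1 under median-ratio scaling); Aldh3a2 fell by 2.14. Camera's adjusted p was 1.1e-08, 0.00139 and 0.00408 for these lists, and adjusted p = 0.763, 0.792 and 0.763 with an estimated correlation.

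Pericentral hepatocyte genes, which Wnt signals keep on around the central vein, had 15 of 19 lower, 0 higher and 4 not called, with 17 lower when adjusted over the list alone (11 under median-ratio scaling); Lgr5 fell by 1.08 and Rgn by 1.15. Drug-metabolising enzymes had 16 of 25 lower, 4 higher and 5 not called, with 18 lower and 4 higher when adjusted over the list alone. Periportal genes went both ways, with 7 of 20 higher, 6 lower and 7 not called and the same split adjusted over the list alone (7 and 2 under median-ratio scaling). The urea cycle genes Arg1 and Asl rose by 0.95 and 1.18 while Hsd17b6 fell by 2.18. Camera's adjusted p was 0.000474 for the pericentral list and 0.041 for the drug list, with adjusted p = 0.763 and 0.792 with an estimated correlation; the drug list had 0.0547 in the fit of 9 libraries. Bile acid synthesis and transport had 10 of 18 lower, 2 higher and 6 not called, with 12 lower and 2 higher when adjusted over the list alone, and camera's adjusted p was 0.0577. Nr0b2, the bile acid sensor's target SHP, fell by 2.08.

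Lipid synthesis went both ways. Fatty acid and triglyceride synthesis had 6 of 21 members higher, 4 lower and 11 not called, with 7 higher and 8 lower when adjusted over the list alone. Thrsp rose from 102 ± 21.0 to 439 ± 138 FPKM (log2 fold change 2.06, SE 0.25) and Scd1 by 0.84, while Fads1 fell by 0.84. Lipid uptake and droplets had 5 of 21 higher, 8 lower and 8 not called, with the same 5 and 8 adjusted over the list alone; Fabp1 fell by 1.53 and Plin3 rose by 0.96. Lipoprotein assembly had 2 of 21 higher, 9 lower and 10 not called, with 2 and 9 adjusted over the list alone (3 and 3 under median-ratio scaling). Glucose metabolism had 5 of 20 higher, 4 lower and 11 not called, and the same counts adjusted over the list alone (5 and 2 under median-ratio scaling); Tat rose by 1.73 and Irs1 fell by 1.28. Methionine and one-carbon metabolism had 6 of 20 higher, 6 lower and 8 not called, with 8 and 6 adjusted over the list alone (9 and 3 under median-ratio scaling). Mat1a, which makes the methyl donor S-adenosylmethionine, rose by 1.16 and Nnmt by 2.77.

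Ribosomal protein genes had 23 of 30 lower, 0 higher and 7 not called, with 24 lower when adjusted over the list alone. Under median-ratio scaling 5 were lower and the median log2 fold change was -0.25 in place of -0.43. In ethanol-fed liver 1, 5 list members lay over 4-fold below every other library. Without those members the list's mean was -0.39 in place of -0.66, and camera's unadjusted p went from 1.3e-05 to 5.9e-06. The list's adjusted p was 9.6e-05, and adjusted p = 0.763 with an estimated correlation. Of 20 m6A genes, 1 was higher, 1 lower and 18 not called, with 1 higher and 0 lower adjusted over the list alone (4 and 0 under median-ratio scaling). Igf2bp2, an m6A reader, rose by 0.72 (SE 0.13), from 0.475 ± 0.0566 to 1.44 ± 0.403 FPKM. Camera gave the m6A list 0.0479, and adjusted p = 0.792 with an estimated correlation. Its adjusted p was 0.0764 without pair-fed liver 1, 0.0509 without pair-fed liver 2, 0.209 without ethanol-fed liver 2 and 0.134 without ethanol-fed liver 3. In the fit of 9 libraries it was 0.0626, and fry gave 0.341.

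Mitochondrially encoded transcripts had 1 of 13 higher, 0 lower and 12 not called, with 0 called over the list alone (4 higher under median-ratio scaling), camera's adjusted p 0.033 and adjusted p = 0.773 with an estimated correlation. Without pair-fed liver 2 it was 0.0659 and without ethanol-fed liver 3 it was 0.105. Nuclear-encoded oxidative phosphorylation had 1 of 24 higher, 2 lower and 21 not called, with 0 called over the list alone (1 higher and 0 lower under median-ratio scaling). Oxidative stress and NRF2 targets had 5 of 22 higher, 7 lower and 10 not called, with 5 and 8 adjusted over the list alone (5 and 5 under median-ratio scaling); Gclm fell by 1.15. Targets of p53 and apoptosis genes had 6 of 18 higher, 4 lower and 8 not called, with the same 6 and 4 adjusted over the list alone (6 and 2 under median-ratio scaling). The cell cycle inhibitor Cdkn1a rose from 1.68 ± 0.604 to 23.3 ± 8.80 FPKM (log2 fold change 3.14, SE 0.28). The cell cycle list had 1 of 4 higher, 2 lower and 1 not called, with 1 and 3 adjusted over the list alone (1 and 1 under median-ratio scaling). Autophagy and lysosome genes had 1 of 21 higher, 3 lower and 17 not called, with 1 and 2 adjusted over the list alone (5 and 2 under median-ratio scaling); Ctsl rose by 1.33. Clock genes had 1 of 16 higher, 7 lower and 8 not called, with 1 and 7 adjusted over the list alone, among them Nr1d1 at -1.93. Male-biased genes had 1 of 13 higher and 3 lower, with the same counts adjusted over the list alone. Female-biased genes had 1 of 18 higher and 6 lower, with 1 and 9 adjusted over the list alone. The sample labels give no sex, fasting state or time of tissue collection, which bear on the clock and sex-biased lists. Camera called none of the lists in this paragraph other than the mitochondrial one, with adjusted p from 0.0822 to 0.76. In all, camera called 12 of 38 lists, and median-ratio scaling 16 with the same 12 among them. Other groupings of the same livers gave as many list calls, up to 14.

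Among inflammatory genes, the cytokine, chemokine and NF-kB list had 3 of 17 higher, 3 lower and 11 not called, with 3 and 4 adjusted over the list alone (4 and 1 under median-ratio scaling). Interferon-stimulated genes had 5 of 26 lower, 0 higher and 21 not called, with 1 lower when adjusted over the list alone (3 under median-ratio scaling); Irf1 fell by 0.80. Matrix and fibrosis genes had 4 of 15 higher and 0 lower, with 3 higher when adjusted over the list alone; Col4a2 rose by 0.71. The neutrophil list had 2 of 5 higher, 0 lower and 3 not called, with 4 higher when adjusted over the list alone, and Lcn2, which hepatocytes also make in the acute phase, is one of the called members. Its camera adjusted p was 0.00408, with adjusted p = 0.763 with an estimated correlation, and 0.0535 without ethanol-fed liver 3. S100a8, the other called member, went from 2.13 ± 1.14 to 15.7 ± 11.1 FPKM (log2 fold change 2.10, SE 0.67; adjusted p 0.0458). Ethanol-fed liver 1 had 2.94 FPKM of S100a8 against 21.2 and 23.0 in the other ethanol-fed livers. Without it the log2 fold change was 2.95. The call was lost without pair-fed liver 1 (1.82), pair-fed liver 2 (2.12), pair-fed liver 3 (2.36), ethanol-fed liver 2 (1.70) or ethanol-fed liver 3 (1.65).

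Kupffer cell markers had 10 of 14 lower, 1 higher and 3 not called, with 12 lower and 1 higher when adjusted over the list alone; Adgre1 and Folr2 fell by 0.93 and 0.81, and 8 members were lower under median-ratio scaling. Sinusoidal endothelial markers had 8 of 14 lower, 1 higher and 5 not called, with 9 and 1 adjusted over the list alone (5 and 2 under median-ratio scaling); Dnase1l3 fell by 1.19 and Lyve1 rose by 1.90. Stellate cell markers had 5 of 12 lower and 1 higher, with 6 and 1 adjusted over the list alone (2 and 1 under median-ratio scaling). Monocyte-derived macrophage markers had 2 of 4 lower and 0 higher, T and NK cell markers 2 of 3 lower and 0 higher (1 lower under median-ratio scaling), each with the same counts adjusted over the list alone. Cholangiocyte markers had 1 of 5 higher (Sox9, by 0.76), erythroid markers 1 of 6 higher and hepatocyte markers 3 of 15 higher and 3 lower, again with the same counts adjusted over the list alone. B and plasma cell, platelet, adipocyte and pancreatic acinar markers had fewer than 3 members above the FPKM minimum.

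**Figure D3:**
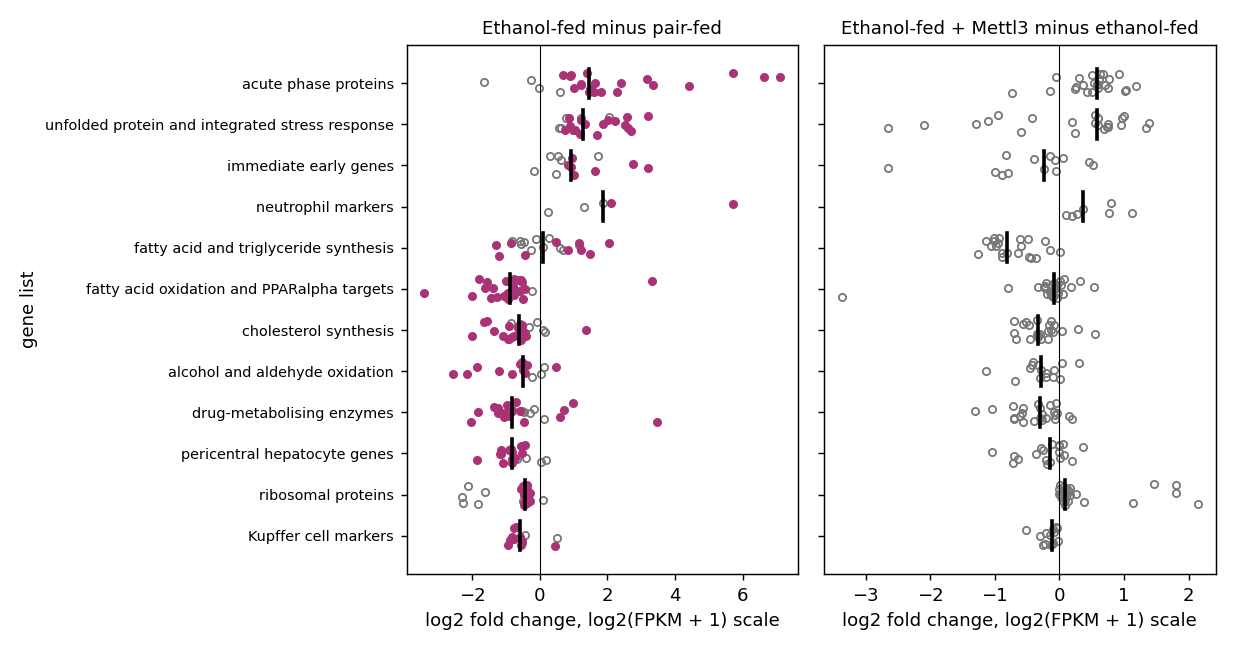
Log2 fold changes, on the log2(FPKM + 1) scale, of the members of 12 gene lists, for ethanol-fed minus pair-fed livers (left) and for Mettl3 minus control virus under ethanol (right). Each point is a gene, filled where limma's adjusted p is below 0.05, and bars mark list medians. Acute phase genes have a median of 1.47 on the left, and no listed gene is filled on the right.

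The second comparison asked what added Mettl3 changed in ethanol-fed livers. Mettl3 itself rose, from 4.69 ± 0.842 to 32.2 ± 6.81 FPKM (log2 fold change 2.54, SE 0.19; n = 3 each). It was higher in 3 of 3 Mettl3 livers, with limma's adjusted p at 0.0257 and a range of 0.001 to 0.238 over the alternatives. No other gene of the 9706 tested passed, while 723 had an unadjusted p below 0.05, and limma-voom on the recovered reads also gave 1 call. The call was lost, at adjusted p of 0.201, 0.137, 0.16 and 0.107, without ethanol-fed liver 2, ethanol-fed liver 3, Mettl3 liver 1 or Mettl3 liver 3. Without ethanol-fed liver 1 there were 2 calls. The authors' table lists 101 genes at q under 0.05, 17 higher and 84 lower. Of the 74 tested here, all 74 had the same sign and an unadjusted p below 0.05 in limma here. They were selected by a test of the same livers, so this is not independent support.

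The lower genes with the smallest unadjusted p, none of which passed in the main fit, were led by Rgs16, a regulator of G protein signalling. It was at 137 ± 78.2 FPKM with the control virus and 7.99 ± 3.18 with Mettl3 (log2 fold change -3.87, SE 0.41; limma's adjusted p 0.151). Every Mettl3 liver lay below every control-virus liver. Klf10, a zinc finger factor, was at 36.7 ± 9.91 and 7.48 ± 2.71 FPKM (-2.17, SE 0.29), and Tcim at 31.0 ± 7.64 and 11.3 ± 1.34 FPKM (-1.36, SE 0.18). Sowahb and Maff had log2 fold changes of -0.94 and -1.11. On the higher side, Zfp970, the complement gene C8a, Etfbkmt, the heat shock gene Hsph1 and Sertad3 had log2 fold changes of 0.82, 0.75, 0.73, 0.83 and 0.58, with adjusted p from 0.453 to 0.569. Of these 10 genes, Rgs16 and Tcim were called in the fit of 9 libraries (adjusted p 0.0156 and 0.0384), and Rgs16 and Klf10 with library quality weights (0.023 for both). All 10 passed in the authors' DESeq2 test of the same livers, with q from 4.41e-20 for Rgs16 to 0.0169 for Sertad3. Whether these genes are called therefore depends on the test.

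Members of the fatty acid and triglyceride synthesis list tended to lie lower, though the livers overlapped. The list's mean log2(FPKM + 1) was 4.57 and 4.80 in Mettl3 livers 1 and 2 but 5.70 in Mettl3 liver 3, against 6.13, 5.78 and 5.29 in ethanol-fed livers 1, 2 and 3. Of 21 members, 20 had a negative log2 fold change, 7 had an unadjusted p below 0.05 and 0 were called, also when adjusted over the list alone; the median was -0.82 (-0.76 under median-ratio scaling). Pnpla3, a lipid droplet enzyme, was at 2.67 ± 0.921 and 0.882 ± 0.300 FPKM (-0.94, SE 0.21), and Scd1 at 2666 ± 307 and 1757 ± 302 FPKM (-0.61, SE 0.18). Acute phase proteins lay higher, at a median of 0.58 with 21 of 24 positive and 2 at an unadjusted p below 0.05. Camera's adjusted p was 4.3e-06 for both lists, with adjusted p = 0.892 with an estimated correlation, as for every list called in this comparison. The acute phase list rested on ethanol-fed liver 1, without which its adjusted p was 0.131.

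Camera called 8 further lists at the preset correlation, all with 0 called members apart from Mettl3. Drug-metabolising enzymes had a median of -0.30, cholesterol synthesis -0.33, alcohol and aldehyde oxidation -0.28, autophagy and lysosome -0.22, lipid uptake and droplets -0.14 and female-biased genes -0.56. Ribosomal proteins had a median of 0.09 and the m6A list 0.08. The m6A list holds Mettl3 itself, which the virus supplied. Mettl3 was the only 1 of its 20 tested members with an unadjusted limma p below 0.05. The list was not tested without Mettl3, so its call says nothing on the other members. Calls were lost for the m6A list without ethanol-fed liver 1 (0.287) or Mettl3 liver 2 (0.115), and for female-biased genes without ethanol-fed liver 1 (0.123), ethanol-fed liver 3 (0.0633) or Mettl3 liver 3 (0.109). They were lost for cholesterol synthesis without ethanol-fed liver 2 (0.139) or Mettl3 liver 3 (0.18), and for alcohol and aldehyde oxidation without ethanol-fed liver 3 (0.0633) or Mettl3 liver 1 (0.204). Lipid uptake and droplets lost it without ethanol-fed liver 3 (0.151), Mettl3 liver 1 (0.0526) or Mettl3 liver 3 (0.109). The ribosomal mean was 0.36, and 0.10 without the 5 members low in ethanol-fed liver 1, where camera's unadjusted p went from 1.1e-05 to 0.000178. Fry called 0 of the 37 lists. Other groupings of the 6 livers gave as many list calls, up to 14. The other 27 lists had camera adjusted p from 0.0539 to 0.883 and medians from -0.36 to 0.58. Adjusted over the list alone, 1 male-biased gene was higher, and 4 immediate early genes and 1 gene each of the fatty acid oxidation, glucose and clock lists were lower.

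**Figure D4:**
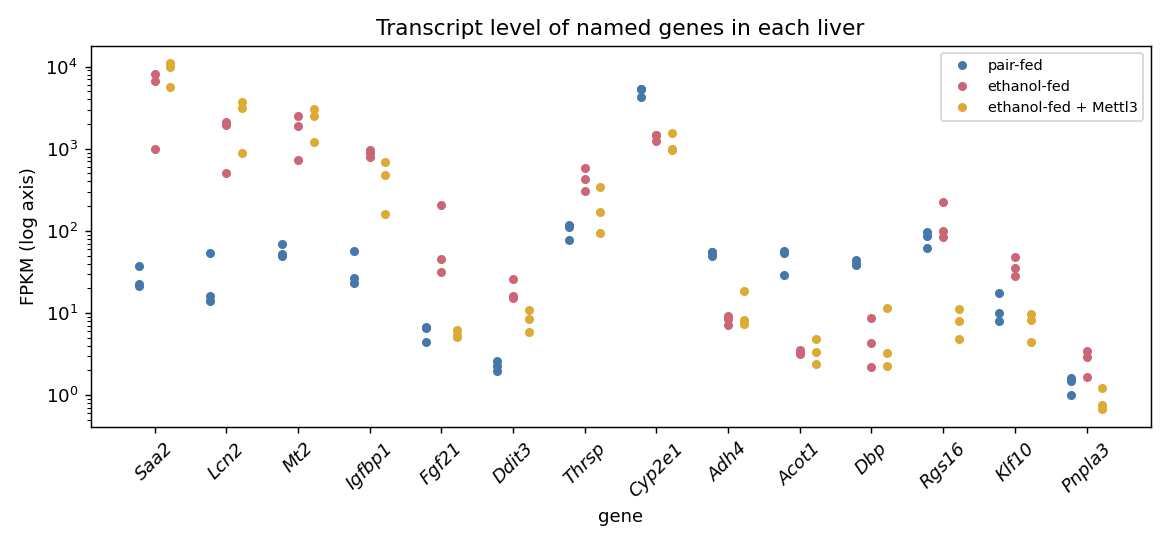
FPKM of 14 named genes in each liver, on a log axis, with 3 points per group. For Rgs16 the Mettl3 livers lie between 4.76 and 11.1 FPKM and the control-virus ethanol-fed livers between 85.1 and 227. For Saa2 ethanol-fed liver 1 lies at 994 FPKM, below the other ethanol-fed livers.

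The third comparison asked how far ethanol-fed livers with added Mettl3 still differed from pair-fed ones. Mettl3 was at 32.2 ± 6.81 against 3.48 ± 0.447 FPKM (log2 fold change 2.87, SE 0.17). Saa2 was at 8864 ± 2843 against 27.0 ± 8.91 FPKM (8.29, SE 0.69) and Lcn2 at 2562 ± 1482 against 28.0 ± 22.3 (6.49, SE 0.73). Cyp2e1 was at 1171 ± 330 against 5021 ± 610 FPKM (-2.13, SE 0.19) and Adh4 at 11.2 ± 6.12 against 52.97 ± 3.18 (-2.25, SE 0.27). Fgf21 was at 5.59 ± 0.588 against 5.89 ± 1.22 FPKM (-0.05, SE 0.56) and was not called, with adjusted p at 0.947. In limma the other 5 had adjusted p of 0.000139, 0.000172, 0.000617, 0.000212 and 0.000744. These genes other than Mettl3 are the ones named for the first comparison.

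Of 10229 genes tested, 4996 passed, 1424 higher and 3572 lower, and 5777 had an unadjusted p below 0.05. The median log2 fold change was -0.18, and median-ratio scaling gave 2380 higher and 2436 lower, 50.6% lower in place of 71.5%. The higher count was 944 without pair-fed liver 3. Acute phase proteins had 20 of 24 higher and 0 lower, with 21 higher adjusted over the list alone. The unfolded protein and integrated stress response had 18 of 22 higher and 0 lower, with the same count adjusted over the list alone. Neutrophil markers had 6 of 7 higher and 0 lower, with 7 higher adjusted over the list alone. Fatty acid oxidation had 25 of 28 lower, cholesterol synthesis 20 of 25 and pericentral genes 15 of 19, with 25, 21 and 17 lower adjusted over the list alone and 24, 15 and 12 under median-ratio scaling. Interferon-stimulated genes had 17 of 26 lower and 0 higher, also adjusted over the list alone, and Kupffer cell markers 12 of 14 lower, also adjusted over the list alone. Camera called 14 of 38 lists, with adjusted p from 2.3e-15 for acute phase proteins to 0.0347 for bile acid synthesis and transport, and adjusted p = 0.688 to 0.773 with an estimated correlation. The ribosomal list had 19 of 30 lower, 20 adjusted over the list alone, but 3 under median-ratio scaling, where camera's adjusted p was 0.382. The bile acid list had 0.0554 without Mettl3 liver 1, and the female-biased list 0.0532 without Mettl3 liver 3.

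Whether Mettl3 moved livers back toward the pair-fed state was measured along the axis from the pair-fed mean (0%) to the mean of both ethanol-fed groups (100%), each virus weighted alike, over 10229 genes. Control-virus ethanol-fed livers lay at 67.5%, 104% and 100%, and Mettl3 livers at 120%, 128% and 81.1%. The difference of the group means, Mettl3 minus control virus, was 19.3 points and had an exact two-sided permutation p of 0.4, where the smallest possible is 0.1. Log2 fold changes of the ethanol and Mettl3 effects had a covariance of 0.0218 and a Pearson's r of 0.137 across 9566 genes, which are not independent replicates. Both effects share the ethanol-fed livers with opposite sign. With no effect at all 100 simulated draws gave a mean covariance of -0.0172. Another case set both ethanol-fed groups to their common mean, an ethanol effect with no Mettl3 effect. It gave -0.0167, from -0.118 to 0.0678 over the central 95%, and 23 of 100 draws were as high as observed. All draws used a spread pooled over the 9 livers. Pair-fed livers correlated with each other at 0.991 to 0.994, and control-virus ethanol-fed livers at 0.972 to 0.986. The draws may therefore understate the spread of the shared ethanol-fed livers. Without Mettl3 liver 2 the observed covariance was -0.00209, and without Mettl3 liver 3 it was 0.0607. No gene was called in both effects here. Of genes called with ethanol, 117 had an opposite and 167 the same direction with Mettl3 at an unadjusted p below 0.05. The draws with no Mettl3 effect gave means of 170 and 131. Single livers turned this balance. The counts, opposite then same, were 84 and 66 without ethanol-fed liver 1 and 176 and 79 without ethanol-fed liver 3. They were 87 and 46 without Mettl3 liver 1 and 92 and 47 without Mettl3 liver 2. Leaving out Mettl3 liver 3 gave 115 and 715, and ethanol-fed liver 2 gave 112 and 144. Leaving out any pair-fed liver kept more in the same direction. The test against a 1.2-fold change gave 35 and 16. Per the values the authors gave, 63 genes pass q of 0.05 in both, 52 in opposite directions and 11 in the same direction. Mettl3 itself is among the 11. Of the 52, 46 were higher with ethanol and lower with Mettl3. Independent lists would share 12.2, a value that leaves out the shared livers. These favour opposite directions, so part of the excess may come from them and the counts alone do not show a reversal.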

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

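Median-ratio scaling, voom on recovered reads with either scaling, library quality weights, the 50-read filter and the fit of 6 libraries were chosen after seeing the data. Voom on recovered reads called 3620, 1 and 5008 genes in the comparisons, against 3625, 1 and 4996. No named gene of the ethanol and Mettl3 comparisons changed sign with a call under any alternative run. For ethanol-fed against pair-fed livers, testing against a 1.2-fold change left 1184 calls, 328 higher and 856 lower, as that test asks for more. Leaving out a library gave 1538 to 4743 calls, 408 to 1098 higher and 1130 to 3645 lower. Median-ratio scaling gave 1729 higher and voom with it 1751, against 1009, since it moves every fold change up. Mettl3 gave 0 to 2 calls without a library, 0 with no filter, 3 in the fit of 9 libraries and 4 with quality weights. Mettl3's own log2 fold change stayed between 2.40 and 2.83, with adjusted p of 0.0875 with no filter, where more genes were tested, and 2.40 to 2.70 without a library. In ethanol-fed livers Mettl3 reached 0.48 with median-ratio scaling (adjusted p 0.0175), 0.60 with voom and that scaling (0.0202) and 0.38 with quality weights (0.037), and 0.24 to 0.46 without a library; the range of adjusted p was 0.0175 to 0.707. For Mettl3 against pair-fed livers a 1.2-fold test left 2164, 618 higher and 1546 lower; median-ratio scaling gave 2380 higher and voom with it 2386, while quality weights gave 7605, 2333 higher. Leaving out a library gave 3342 to 5678, of which 944 to 1598 were higher.

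In the fit of 9 libraries 1 gene was called in both effects, in opposite directions. With median-ratio scaling, with voom and that scaling, or at an adjusted p under 0.1, the 1 gene was Mettl3 itself, higher in both. Quality weights gave 3 such genes, 2 of them in opposite directions, and leaving out a library gave 0 to 1. An estimated correlation left 0 gene lists in each comparison. Fry called 10, 0 and 22, and with no filter camera called 19 for ethanol. The cause of the changes under quality weights and fry was not tested.

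With the replicate number as a block, calls went from 3625 to 2778 for ethanol and from 1 to 0 for Mettl3, whose log2 fold change of 2.54 had adjusted p 0.238. Correlations of same-numbered livers ran from -0.412 to 0.394, and 3 of 9 libraries correlated best with their own number, so the livers share only a number.

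Of 136 called genes that the naming rule selected in the ethanol comparison, 97 to 132 were called without a given library and none changed sign. Depth was 34656256 to 38159563 reads per library, and genes below the FPKM minimum were tested only with no filter or the 50-read filter.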

Other observations

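The tests of scaling, of ethanol-fed liver 1 and of the response to sugar, together with the time since feeding, were chosen only after the results were seen; sugar genes were listed after related lists and the authors' calls had been looked at. In all, 42 lists in 3 comparisons and 3 patterns were examined.

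For each comparison 10 splits of 6 libraries exist, too few for a share under 0.05. Ethanol gave 3625 calls against 0 in the highest other split (1 split as large, the real one), and Mettl3 against pair-fed livers 4996 against 0 (1 split). The Mettl3 effect gave 1 call against 2, with 2 splits as large. For gene lists, ethanol gave 12 against 14, with 3 splits as large, and Mettl3 10 against 14, with 7 splits as large. List calls at the preset correlation therefore did not set the real grouping apart from the others, for ethanol or for Mettl3.

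More genes were lower than higher in ethanol-fed livers, 72.2% of calls. A few abundant genes taking the reads stays open. The 20 most abundant genes held 26.6% to 29.0% of reads in pair-fed and 31.9% to 34.1% in ethanol-fed livers. After rescaling without them the median log2 fold change went from -0.14 to -0.053, just outside the 0.05 set beforehand, and 58.7% of calls were lower. Without the 50 most abundant the median was 0.00 and 50.3% of calls were lower. Scaling by total reads stays open too. Under median-ratio scaling 50.8% of calls were lower, but that scaling sets the median near 0 by construction and so cannot decide. A lower RNA output of many genes in ethanol-fed livers, the biological alternative, may underlie it and was not tested.

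Ethanol-fed liver 1 stood apart from the other ethanol-fed livers, at 67.5% on the axis from the pair-fed mean to the mean of both ethanol-fed groups. That it is a pair-fed liver was argued against, since 93.9% of 836 genes called without it at 2-fold or more lay beyond the pair-fed range on the ethanol side. Reads missing from a few genes was tested as the cause of its position. Without the 9 genes over 4-fold low in it, that position was 66.2%. All 9 were also lower in ethanol-fed livers 2 and 3 than in every pair-fed liver. Their low values pull liver 1 toward the ethanol end, the opposite of what that cause needs. Leaving them out could hardly raise its position, so the test could not have favoured that cause. A mixture of ethanol-fed and pair-fed RNA could not be decided: 35 genes lay over 2-fold outside the range of the other 5 libraries, against 22 and 16 for the other ethanol-fed livers. A milder response of that mouse may be a further explanation and was not tested. Over those 836 genes its median change was 63.8% of that of the other ethanol-fed livers. However, 90 genes exceeded 100%, so not every gene moved less. On PC2 it lay at 32.9, against 8.12 and 1.76 for ethanol-fed livers 2 and 3. Mettl3 liver 3 also lay apart from its group, at 7.99 on PC1 against 35.3 and 41.1 for Mettl3 livers 1 and 2. On the axis Mettl3 liver 3 lay at 81.1%, against 120% and 128% for those livers.

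Sugar-responsive genes tended to lie lower with Mettl3. As a hypothesis, a weaker response to dietary sugar may explain it: the list's median log2 fold change was -0.30, 16 of 16 members were negative and 0 had an unadjusted p below 0.05, with camera p at 0.0307 and 0.466 with an estimated correlation. It stays open, since 4 of the 10 splits gave a camera p as small, the smallest of the others was 1.1e-05, and without ethanol-fed liver 1 the median was -0.17 with 14 negative. A longer time since feeding stays open too, at a median of -0.089 for fatty acid oxidation genes. Livers taken at another time of day cannot be told apart, since the clock contrast differed by 0.0751 between Mettl3 and ethanol-fed livers but rests on 1 morning gene.

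In ethanol-fed liver 1, 9 genes lay over 4-fold below every other library, a rule chosen after their values were seen: Eef1a1, Hamp, Rpl13, Rpl26, Rplp0, Rps18, Rps2, Rps3 and Rps3a1. Eef1a1 was at 24.0 FPKM there and at least 1649 elsewhere, and Rplp0 at 2.25 FPKM and at least 193 elsewhere. Of 76 ribosomal protein genes, 7 were that low, and the others differed by a median log2 of 0.09. No other library had more than 1 gene so low.

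Mean log2(FPKM + 1) of 7 neutrophil markers was 1.39 to 1.62 in pair-fed livers. It was 2.20, 3.79 and 4.00 in ethanol-fed livers 1, 2 and 3, and 4.06, 4.28 and 3.20 in Mettl3 livers 1, 2 and 3. Lcn2, which hepatocytes also make in the acute phase, is a member. In ethanol-fed liver 1 Lcn2 was at 506 FPKM, against 13.9 to 53.7 in pair-fed livers. S100a8, S100a9 and Retnlg were at 2.94, 4.52 and 0.902 FPKM in that liver, within the pair-fed range of each. The mean does not by itself show a neutrophil rise in that liver. The contrast of 8 evening clock genes to 1 morning clock gene, ethanol-fed minus pair-fed, was -0.77 on the log2 scale. Its exact permutation p was 0.1, the smallest possible, and it rests on that 1 morning gene.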
